A study of Mus musculus with 6 samples.

How the data were processed

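Total RNA of 6 sorted samples of P14 cytotoxic T cells, 3 GFP positive and 3 GFP negative, was labelled with biotin and hybridised to Affymetrix whole-genome mouse arrays, 1 per sample, per the labels' protocols. The deposited table holds log2 signal values for 45101 probe sets on each array, and the log2 unit was read from the range of the values. The submitters' processing notes name Affymetrix Expression Console, without a version. The algorithm that summarised probes, its background treatment and the normalization between arrays are not given in the sources used here, and no detection calls were used here. Groups and replicate numbers were taken from the sample labels.

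The deposited values were used without further normalization. Of the probe sets, 64 are controls, 34945 carry 1 gene symbol, 932 carry several and 9160 are not listed in the table that pairs probe sets with genes. Those with several symbols or none name no gene here. Of the listed probe sets, 34741 matched a gene of the mouse reference table (assembly GRCm38.p6), which updated 0 symbols. No genome build is named for the array, so no coordinates are given. Each of 18193 genes was represented by the probe set with the highest mean over the 6 arrays. Genes under the 40th percentile of mean log2 signal over all probe sets other than controls, a level of 1.27, were left out, which leaves 13194. Among second probe sets of the called genes, 83.7% of 4867 changed in the same direction, 2116 passed the threshold the same way and 59 the opposite way. Some genes of the fixed lists are not reported here.

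GFP positive samples were compared with GFP negative samples using limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The test, the filter, the rule for named genes, the gene lists and most alternatives were chosen before the data were examined. The rule names Hdac7 and Il2ra, then the 12 genes with the largest change in each direction among those past the threshold whose groups do not overlap, then up to 4 members of each list by unadjusted p and any list member past the threshold, then the control probe sets and the 3 brightest markers of each other cell type. Members of a list that did not pass and are given with their values, such as Cish, Tbx21, Pdcd1, Lag3, Icos, Cd44, Pgk1, Ldha, Hk2, Lyz2, Cd4, Egr1, Oas1a, Mx2 and the Mcm genes, were chosen after their values were seen.

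Gene lists were 17 for T cell programs and 8 for markers of other cell types, and the 23 with at least 5 tested members were compared with the other genes by camera at a preset correlation between genes of 0.01, adjusted over the lists. Counts over each list are also given adjusted over the list alone. Some genes stand in more than 1 list, and 3 of the other-cell markers are also in a program list. Camera with the correlation estimated per list called 0 lists at the threshold, against 5 with the preset correlation, and fry, which tests whether the genes of a set move on balance one way and does not compare them with other genes, called 9. Among lists added later, TGF-beta and ER chaperone genes also lost their calls, though their estimates, -0.02 and -0.03, lay below the preset. A higher correlation therefore does not account for every lost call. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom, in place of a number set by the genes tested. For the HDAC family list, with an estimate of 0.0016, the unadjusted camera p went from 0.272 to 0.315. The lost calls therefore do not measure correlation between genes alone. RNA quality measures were compared by exact permutation tests, where 3 samples against 3 cannot give a p under 0.1. These tests treat the 6 samples as exchangeable and so ignore any pairing by replicate number. A paired exact test over all sign flips within replicate numbers, added after seeing the data, cannot give a p under 0.25.

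The procedure was tested on simulated data with the real arrays' means and spread, with 200 of 13194 genes changed. It recovered 41% of genes changed by 0.5 on the log2 scale and 82% of those changed by 1. False calls made up 2.38% of calls, a raised list was called, and 0 of the other lists were. Noise was drawn independently for each gene and sample, without correlation between genes or pairing by replicate number. Far fewer genes were changed than were called in the data. The simulation therefore cannot show how the list test or the false calls behave with correlated genes.

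The groups share the replicate numbers 1 to 3 in the labels. Samples with the same number deviated together from their group means, with correlations across genes of 0.47, 0.35 and 0.25, and each sample correlated best with its own number. This is what pairing by number would give. The labels do not state such pairing, and with 3 numbers the same order can arise by chance. With the replicate number as a block, 5858 genes changed (3371 higher, 2487 lower). The alternatives chosen beforehand were this block, other filters on dim genes, quantile normalization, median centring, log2(2^value + 32) in place of the value, an intensity trend with a robust prior, array weights, other ways to pick a gene's probe set, other thresholds, other list tests and leaving out each array. A filter at a level of 5, cyclic loess normalization and leaving out GFP negative 1 with GFP positive 3 were added after seeing the data, as were 11 further gene lists for the closing observations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.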

Results

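Transcripts were measured on Affymetrix whole-genome mouse arrays in P14 cytotoxic T cells, whose transgenic T cell receptor recognises the gp33 peptide of lymphocytic choriomeningitis virus. Spleen cells of C57Bl/6 mice were activated with that peptide for 24 h and infected with a retrovirus encoding a phosphorylation-deficient form of HDAC7 tagged with GFP. HDAC7 is a class IIa histone deacetylase that represses transcription in the nucleus, and its phosphorylation leads to its export to the cytoplasm. Sorting on GFP gave 3 samples of GFP positive cells, which carry the mutant, and 3 samples of GFP negative cells, which serve as the control. The control cells therefore come from the infected cultures, and cells with an empty vector were not analysed here. The labels call the 3 samples of each group biological replicates, but do not state whether they came from separate animals or cultures, so p-values measure only the spread between these samples. The number of arrays limits the precision. The median log2 signal per array was 1.63 to 1.72, and the TrpnX control probe sets, which match no mouse transcript, averaged 0.64 in GFP negative and 0.66 in GFP positive samples, so signals near those values lie close to background.

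The comparison of GFP positive with GFP negative cells asks how the HDAC7 mutant alters gene expression in activated cytotoxic T cells. GFP positive cells had 9.95-fold more signal on an Hdac7 probe set, 4.96-fold less Il2ra (the alpha chain of the interleukin 2 receptor) and 11.3-fold less of the survival kinase gene Pim2. The integrin gene Itgae rose from a level near background, the transcription factor gene Klf2 fell to a level 9.24-fold lower, and the granzyme gene Gzmb was 2.00-fold lower while Prf1 (perforin) was 2.83-fold higher. With 32 added to each value in linear units, the log2 changes of Itgae, Klf2 and Prf1 were 1.39, -1.70 and 0.43, each smaller than as deposited by more than 1.5 times. Of the gene lists, interferon-response genes were higher, with 16 of 19 rising. Lists of sterol and fatty acid synthesis, the cell cycle and T cell receptor signalling were higher by smaller amounts and in part. Of these, 11 of 18, 14 of 25 and 10 of 18 genes rose, and 10 of 16 amino acid supply genes fell. These list calls rest on a preset correlation between genes, and none of them held when camera estimated the correlation per list. Each then had an adjusted p of 0.759, with unadjusted camera p from 0.057 for interferon genes to 0.231 for amino acid genes. That setting also tests with fewer degrees of freedom, so the loss does not measure correlation between genes alone. The calls of the cell cycle and T cell receptor signalling lists also ended with a stricter filter on dim genes.

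The targeted gene was examined in every sample first. The probe set that represents Hdac7 read 4.83 ± 0.03 (log2, SD, n = 3) in GFP negative and 8.15 ± 0.05 (n = 3) in GFP positive cells. The lowest GFP positive sample, at 8.09, lay far above the highest GFP negative sample, at 4.86. This was a rise of 3.32 ± 0.07 (SE) on the log2 scale, with an adjusted p of 9.7e-07 from limma. A second Hdac7 probe set, brighter in the control cells, fell by 0.55, from 6.74 ± 0.08 to 6.19 ± 0.02. The part of HDAC7 that the construct carries is not given in the sources used here, and a probe set outside the part it carries would not detect it. Both Il2ra probe sets fell. The brighter one went from 8.34 ± 0.05 to 6.03 ± 0.23 (limma adjusted p = 2.9e-05), a change of -2.31 ± 0.12 (SE), and the dimmer one changed by -2.36. Il2ra was known to be of interest in this study, so its fall is not independent evidence.

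**Figure D1:**
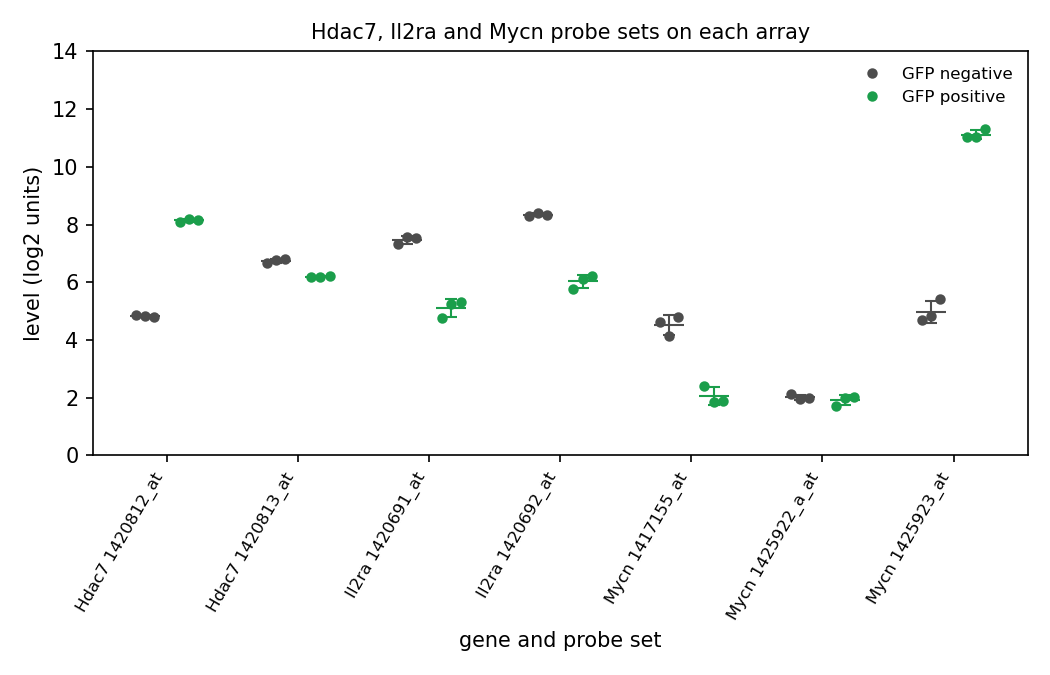
Log2 signal of the probe sets of Hdac7, Il2ra and Mycn on each array, with points for single arrays and bars for the mean ± SD (n = 3 per group). Probe sets of Hdac7 and of Mycn move in opposite directions, by 3.32 and -0.55 for Hdac7, while both Il2ra probe sets lie lower in GFP positive samples.

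Across the array, 5557 of 13194 tested genes (42.1%) changed at the adjusted p threshold, 3248 of them higher and 2309 lower in GFP positive cells. Most changes were small, with a median fold of 1.43 among changed genes. At least 2-fold changes were found for 703 genes, 487 higher and 216 lower. The split between higher and lower calls depended on how arrays were scaled. It was 58.4% higher as deposited, 49.0% after quantile normalization and 39.6% after median centring. That setting centred each array on the median of its probe sets past the dim filter, not of all its probe sets. It moved the median change of all tested genes from -0.02 to -0.14. In 7103 genes (53.8%) the 3 samples of each group did not overlap, against 10% expected for exchangeable samples.

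The largest rises included genes for both partners of an adhesive contact. Itgae, which encodes the alpha E integrin chain (CD103), went from 1.76 ± 0.13 to 5.89 ± 0.71, and its second probe set from 1.97 ± 0.24 to 5.43 ± 0.76. Cdh1, encoding E-cadherin, the ligand of that integrin, went from 0.90 ± 0.26 to 5.15 ± 0.66. The syndecan gene Sdc4 rose from 2.02 to 5.57, Marcks, which encodes a protein kinase C substrate that binds actin, from 1.88 to 6.03, and the transcription factor gene Maf from 1.42 to 4.71. Slc6a19, an amino acid transporter gene, Tmem140 and the carboxypeptidase gene Cpd rose from 1.92, 1.69 and 0.95 to 5.11, 4.78 and 4.03. The control levels of these 8 genes, 0.90 to 2.02, lie low, so no fold is given for them. Lrig1, encoding a negative regulator of receptor tyrosine kinases, rose 8.02-fold, and Mxd4, whose product antagonises MYC, by 2.96 (7.78-fold). The limma adjusted p of these genes lay between 2.95e-05 for Maf and 2.5e-04 for Slc6a19, and in each the 3 GFP positive samples lay above the 3 GFP negative ones.

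The largest rise on a single probe set was that of the brightest of 3 probe sets for Mycn, a MYC-family transcription factor gene, from 4.97 ± 0.38 to 11.11 ± 0.16, or 70.9-fold (limma adjusted p = 3.2e-06). The other Mycn probe sets did not move with it, since a second, at 4.51 in GFP negative cells, changed by -2.47, and the third, at 2.01, by -0.11. These values are therefore reported per probe set and give no direction for the gene.

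The largest falls were in genes of varied function. Pim2, a serine/threonine kinase gene that promotes lymphocyte survival, went from 9.37 ± 0.18 to 5.88 ± 0.20 (11.3-fold lower). Klf2, encoding a factor that maintains quiescence and the expression of lymph node homing receptors, went from 6.79 ± 0.18 to 3.58 ± 0.01, and Lgals3, which encodes galectin-3, from 8.09 ± 0.28 to 4.63 ± 0.05 (11.0-fold lower). Klrk1, encoding the activating receptor NKG2D, was 7.29-fold lower, and Fut4, a fucosyltransferase gene, fell from 4.80 to 1.598, near background. Igfbp4, which encodes a binding protein of insulin-like growth factors, was 9.69-fold lower on its brightest probe set, while its other probe sets changed by -3.06 to -0.39, and the actin-binding gene Coro2a was 7.45-fold lower. Fam71b (13.5-fold), Gpr146 (8.51-fold), Gm17767 (7.29-fold) and Osbpl3 (6.09-fold) were also lower. Adjusted p from limma lay between 2.2e-06 for Fut4 and 4.2e-04 for Klrk1 in these genes. Tg, the thyroglobulin gene, completed the 12 largest falls, from 4.79 ± 1.25 to a low 2.19 ± 0.59 (limma adjusted p = 0.0078), with a wide spread between GFP negative samples.

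The size of a change also differed between probe sets of a gene. Among other probe sets past the dim filter, those of Marcks changed by -0.03 to 3.61, of Maf by -0.03 to 1.62, of Mxd4 by 0.23 to 1.92 and of Cpd by -0.07 to 0.85, and the second of Sdc4, Osbpl3 and Fut4 by 0.80, -0.96 and -0.13. Those of Lrig1, Slc6a19 and Gpr146 changed by 2.68, 2.65 and -3.40. Fold sizes of genes with a low signal depend on the background treatment. When 32 was added to each value in linear units before taking logs, 10 of the 12 largest rises and 10 of the 12 largest falls shrank by more than 1.5 times, for example Cdh1 to 1.02, Cpd to 0.52, Itgae to 1.39, Maf to 0.75, Klf2 to -1.70 and Fut4 to -0.77. Hdac7, the brightest Mycn probe set, Pim2 and Lgals3 did not shrink that far. Among genes given above with a fold, Lrig1, Fam71b, Gpr146 and Klrk1 shrank to 0.99, -1.67, -1.11 and -1.04. Their folds therefore depend on the background treatment too. Tg lost its call (-0.79, limma adjusted p = 0.098), and also with a robust prior that follows intensity (adjusted p = 0.056), while the other 23 genes passed in both settings.

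**Figure D2:**
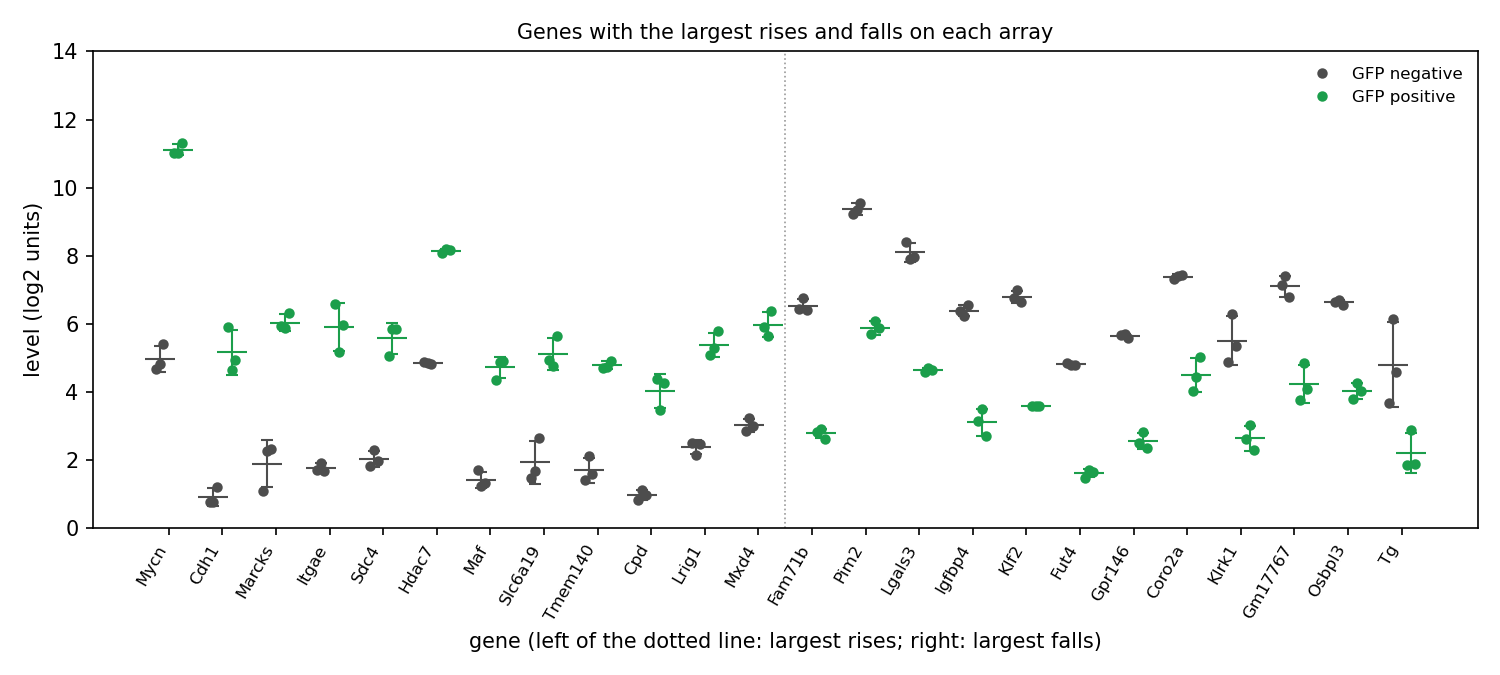
Log2 signal of the genes with the 12 largest rises and 12 largest falls on each array, with points for single arrays and bars for the mean ± SD (n = 3 per group). In each gene the 3 samples of one group lie apart from those of the other, with the lowest control level for Cdh1 at 0.90 and the highest for Pim2 at 9.37.

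Interferon-response genes formed the list with the largest shift. Of 19 members tested, 16 rose, 1 fell and 2 did not pass, both over all genes and adjusted over the list alone, with a median change of 1.34. Usp18, which removes ISG15 from proteins, rose by 2.40 and Isg20, an antiviral exonuclease gene, by 2.39. The RNA sensor genes Ddx58 (RIG-I) and Ifih1 (MDA5) rose by 2.15 and 2.02, the nucleic acid sensor gene Zbp1 by 1.81 and Gbp2, a guanylate-binding protein gene already bright at 9.56 ± 0.43, by 1.34. Irf7 and Irf9, transcription factors of the pathway, rose by 1.92 and 1.38. Oasl1, a negative regulator of Irf7 translation, was the member that fell (-0.42, and -0.07 with 32 added in linear units), and Oas1a and Mx2 had changes of 0.23 and -0.10. Camera gave the list an adjusted p of 1.1e-06, which became an adjusted p of 0.759 with an estimated correlation. With 32 added in linear units the median fell to 0.50, with the list still called, and Usp18, Ifih1, Irf7 and Irf9 rose by 1.44, 1.10, 0.68 and 0.85. Without GFP negative 1 and GFP positive 3, the samples whose control probe sets stood apart, 14 members rose and Oasl1 lost its call.

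Genes of amino acid uptake and synthesis that respond to the transcription factor ATF4 fell as a list. Of 16 tested, 10 fell, 1 rose and 5 did not pass; adjusted over the list alone, 11 fell and 1 rose. Shmt2, a mitochondrial enzyme of serine and glycine metabolism, changed by -1.09 and Psat1, an enzyme of serine synthesis, by -0.96. Aldh18a1, which acts in proline synthesis, changed by -0.68 and the arginine transporter gene Slc7a1 by -0.65. Ddit3 (CHOP), a stress-induced transcription factor gene, rose by 1.05 (0.61 with 32 added in linear units). The list median was -0.52 (camera adjusted p = 7.1e-04, and adjusted p = 0.759 with an estimated correlation).

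Genes of sterol and fatty acid synthesis rose by modest amounts. Of 18 tested, 11 rose, 0 fell and 7 did not pass by limma; adjusted over the list alone, 12 rose and 1 fell. The master regulators Srebf1 and Srebf2 rose by 0.93 and 0.64, the sterol transport gene Stard4 by 0.59 and Lss (lanosterol synthase) by 0.54. Median change was 0.38 (camera adjusted p = 0.0017), with an adjusted p of 0.759 with an estimated correlation. Leaving out GFP negative 1 and GFP positive 3 together lowered the number that rose to 7.

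Cell cycle genes rose in part. Of 25 tested, 14 rose, 1 fell and 10 did not pass; adjusted over the list alone, 14 rose and 2 fell. Among those that rose were Ccnb2 (cyclin B2, 0.83), Aurka (Aurora kinase A, 0.73), Mki67 (the proliferation antigen Ki-67, 0.66) and E2f2, a transcription factor gene of the G1 to S transition (0.68). Ccne1 (cyclin E1) fell by 0.55. The replication licensing genes Mcm2 to Mcm7 and Pcna did not pass, with changes from -0.25 for Mcm4 to 0.17 for Mcm7. The list median was 0.31 (camera adjusted p = 0.017, and adjusted p = 0.759 with an estimated correlation).

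In the T cell receptor signalling list 10 of 18 genes rose, 2 fell and 6 did not pass, the same counts as adjusted over the list alone. The coreceptor genes Cd8a and Cd8b1 rose by 1.24 and 1.15, Plcg1 (phospholipase C gamma) by 0.94 and Prkd2, a protein kinase D gene, by 0.89. The kinase genes Zap70 and Prkcq fell by 0.50 and 0.25. Prkcq lost its call without GFP negative 1, 2 or 3 or GFP positive 2 or 3, with changes from -0.26 to -0.22. The list median was 0.39 (camera adjusted p = 0.027, and adjusted p = 0.759 with an estimated correlation). The calls of this list and of the cell cycle list ended when dim genes under the 60th percentile were left out, at a camera adjusted p of 0.145 for both. Camera compares a list with the other genes, and the median change of all tested genes was 0.06 with that filter, against -0.02 without it.

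**Figure D3:**
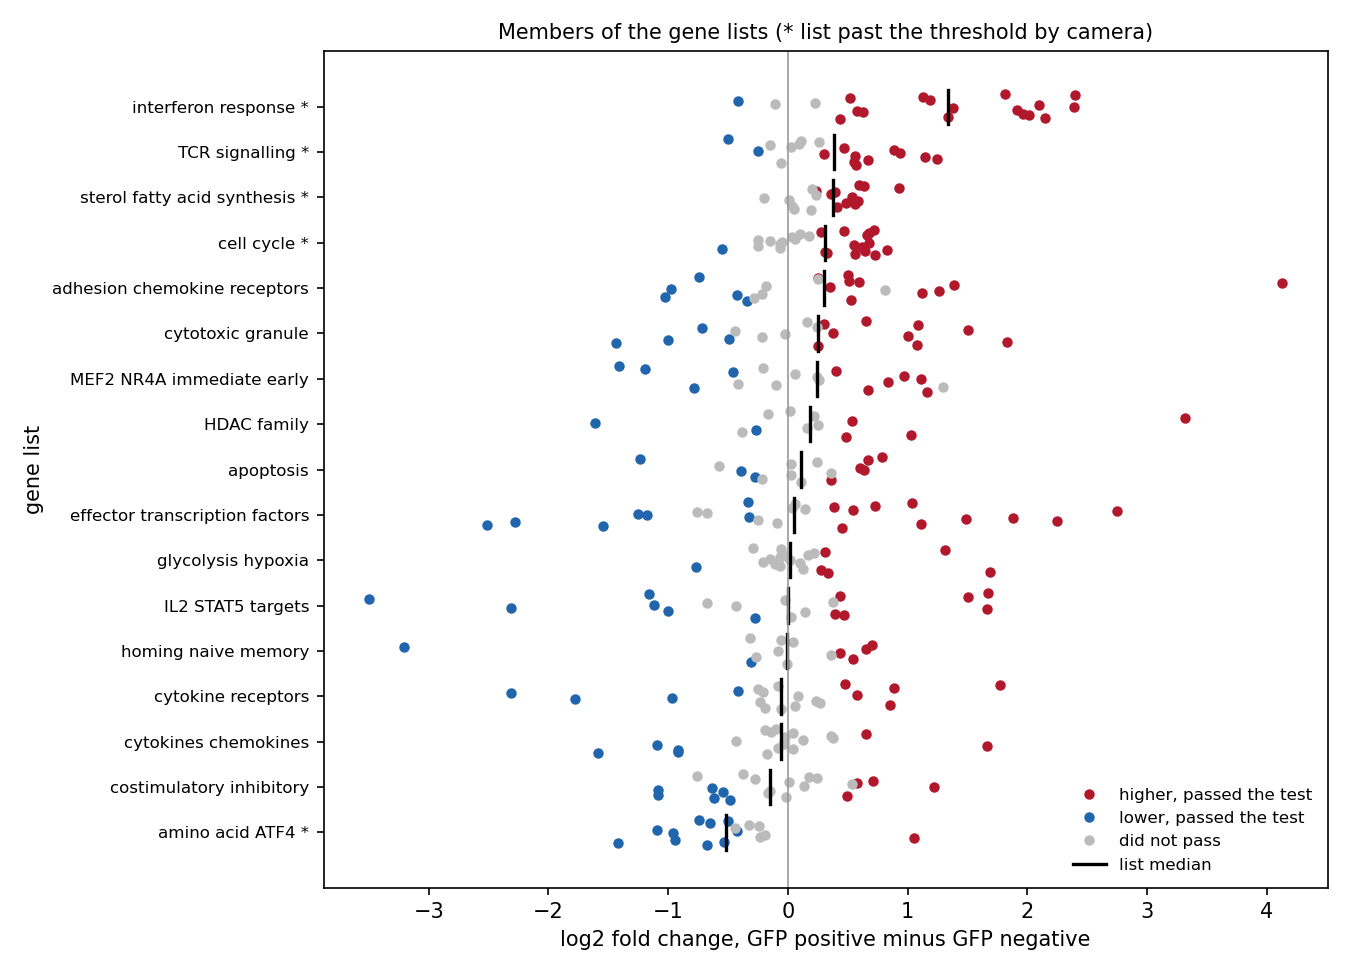
Change of each tested member (log2, GFP positive minus GFP negative) in the fixed gene lists, with members that rose in red, that fell in blue and that did not pass in grey, a black line at each median and an asterisk at lists called by camera. Interferon-response genes have the highest median, at 1.34, and amino acid genes the lowest, at -0.52, and none of the 5 called lists passed with an estimated correlation.

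Genes of cytotoxic granules changed in both directions, with 9 of 18 higher, 4 lower and 5 not passing (9 and 5 adjusted over the list alone; camera adjusted p = 0.538). Gzmb, the granzyme B gene, went from 12.58 ± 0.02 to 11.58 ± 0.16. Gzma (granzyme A) rose by 1.83, Ctsw, a cathepsin gene of cytotoxic cells, by 1.08 and Serpinb9, an inhibitor of granzyme B, by 1.08. Prf1 rose from 2.89 ± 0.29 to 4.39 ± 0.22, a rise of 0.43 with 32 added in linear units. Fasl, which encodes the death ligand of T cells, changed by -1.44 (-0.37 in the same setting).

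Cytokine receptor genes gave 5 rises, 4 falls and 10 that did not pass among 19, with the same counts adjusted over the list alone (camera adjusted p = 0.999). Tgfbr1, a TGF-beta receptor chain, rose by 1.77 and Tgfbr2 by 0.48, and Il10rb, a chain of the interleukin 10 receptor, by 0.85. Both chains of the interleukin 18 receptor were lower, with changes of -1.78 for Il18r1 and -0.97 for Il18rap (-0.95 and -0.53 with 32 added in linear units). Among 18 genes known as targets of interleukin 2 and STAT5 signalling, 6 rose, 6 fell and 6 did not pass (7 and 7 adjusted over the list alone; camera adjusted p = 0.709). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.67, whereas Socs2 changed by -1.16 and Myc by -1.12. Cish, another target of STAT5, changed by 0.14 and did not pass.

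Of 24 transcription factors of effector T cells, 10 rose, 7 fell and 7 did not pass (10 and 8 adjusted over the list alone; camera adjusted p = 0.673). Gata3 rose by 2.25, Id2, an inhibitor of E proteins, by 1.49, Ikzf2 (Helios) by 1.88 and Rora by 2.75. With 32 added in linear units the rises of Gata3, Ikzf2 and Rora were 1.34, 1.06 and 0.74, and Batf3 changed by -1.14. Eomes, which supports memory and effector differentiation, changed by -2.28, the AP-1 factor genes Batf and Batf3 by -1.55 and -2.51, and Irf4 and Irf8 by -1.18 and -1.25. Tbx21, which encodes T-bet, did not pass, at 0.06. Of 13 homing and memory genes, 4 rose, 2 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.859). Itgb7, whose product pairs with the alpha E chain, rose by 0.65, Klf3 by 0.70, Cd27 by 0.55 and Id3 by 0.43. Ccr7, a lymph node homing receptor, fell with Klf2, by 0.31, and lost its call without GFP negative 3 or GFP positive 3 (-0.26 in both).

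Adhesion and chemokine receptor genes numbered 10 higher, 5 lower and 5 not passing of 20, also adjusted over the list alone (camera adjusted p = 0.411). Besides Itgae, Itga4, the alpha chain of VLA-4, rose by 1.39, and the chemokine receptor genes Cxcr3 and Cxcr4 by 1.12 and 1.26. The adhesion gene Cd2 changed by -1.03 and Cxcr6 by -0.98. On the scale with 32 added, Itga4, Cxcr4 and Cxcr6 changed by 0.75, 0.68 and -0.31. Without GFP negative 1 and GFP positive 3 the number lower was 2. Of 21 costimulatory and inhibitory receptor genes, 4 rose, 6 fell and 11 did not pass, also adjusted over the list alone (camera adjusted p = 0.637). Cd28, the main costimulatory receptor, changed by -1.09, the activation marker Cd69 by -1.08 and Cd5, which dampens receptor signals, by -0.54, while the ectonucleotidase gene Entpd1 (CD39) rose by 1.22 and Slamf1 by 0.71. On that scale Cd69, Entpd1 and Slamf1 changed by -0.69, 0.38 and 0.47. Pdcd1, Lag3, Icos and Cd44 did not pass, with changes of 0.01, 0.54, 0.13 and -0.17.

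Secreted cytokines and chemokines mostly did not pass, with 2 of 20 higher, 4 lower and 14 not passing, also adjusted over the list alone (camera adjusted p = 0.637). Ifng, the interferon gamma gene, rose by 1.66 and Tnfsf10 (TRAIL) by 0.65, and the chemokine genes Ccl3, Ccl4 and Ccl5 changed by -1.58, -0.92 and -0.92 and Il10 by -1.10. These genes have low to moderate signals, and with 32 added the changes of Ifng, Ccl3, Ccl4 and Ccl5 were 0.55, -0.19, -0.17 and -0.43, and that of Il10 was -0.21. Tnfsf10 lost its call without GFP negative 1 (0.61), GFP negative 2 (0.66) or GFP positive 3 (0.68), in that setting (0.23), and after quantile normalization (0.52) or median centring (0.54). Without GFP positive 1, 4 genes of the list rose, and 1 rose without GFP negative 1, GFP negative 2 or GFP positive 3.

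MEF2, NR4A and immediate-early genes, some of which class IIa deacetylases are known to repress through MEF2, gave 6 rises, 4 falls and 7 that did not pass among 17 (7 and 5 adjusted over the list alone; camera adjusted p = 0.673). Klf10 rose by 0.97, Dusp1 by 1.16, Jun by 1.11 and Mef2d by 0.40. Nr4a1, an orphan nuclear receptor gene, changed by -1.19, Nr4a3 by -1.41 and Mef2a by -0.45. With 32 added, Klf10, Jun, Mef2d, Nr4a1 and Nr4a3 changed by 0.64, 0.71, 0.24, -0.40 and -0.40. Egr1 differed by 1.29 but varied widely and did not pass (limma adjusted p = 0.071). Within the HDAC family and its corepressors, 4 of 12 rose, 2 fell and 6 did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 0.637). The 4 rises include Hdac7, which the retrovirus encodes and whose second probe set fell. Besides Hdac7, Hdac10, Hdac6 and Hdac1 rose by 1.03, 0.53 and 0.49, and Hdac5, the class IIa relative of Hdac7, changed by -1.61. With 32 added, Hdac5, Hdac10 and Hdac6 changed by -0.61, 0.52 and 0.32. Hdac2 fell by 0.27 and lost its call when any 1 of the 6 samples was left out (-0.31 to -0.22).

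Glycolysis and hypoxia genes gave 5 rises, 1 fall and 13 that did not pass among 19 (4 and 1 adjusted over the list alone; camera adjusted p = 0.637). Aldoc, an aldolase gene, rose by 1.69, the glucose transporter gene Slc2a3 by 1.32 and Aldoa by 0.33, while Pgk1, Ldha and Hk2 did not pass, at -0.02, -0.10 and -0.07. The number that rose was 3 without GFP negative 2, GFP negative 3, GFP positive 1 or GFP positive 2, and Egln3 (-0.77) lost its call without GFP positive 3 (-0.61). Of 15 apoptosis genes, 5 rose, 3 fell and 7 did not pass, also adjusted over the list alone (camera adjusted p = 0.637). Trp53inp1 rose by 0.79, the survival gene Mcl1 by 0.67 and Casp8 by 0.60, and the BH3-only gene Pmaip1 (NOXA) changed by -1.23 (-0.50 with 32 added). The number of apoptosis genes that fell was 1 without GFP negative 2, GFP negative 3 or GFP positive 1. The call of Bcl2 (-0.28) was lost with the replicate number as a block (limma adjusted p = 0.059) and without GFP negative 1, 2 or 3 or GFP positive 1 or 2 (-0.32 to -0.22), and other probe sets of Bcl2 turned its sign.

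Markers of other cell types were examined because a sort of spleen cultures could hold such cells. Of 78 markers on the array, 8 had a mean level of at least 5. Of these, Ctla4 (8.22), Tnfrsf4 and Bst2 are also in other lists, and Ctss (7.96), Cst3 (7.25) and the class II gene H2-Ab1 can be expressed outside the cell type they mark. B cell markers gave 1 of 9 higher, Ighm, at a level of 9.74 and with probe sets that disagreed, and adjusted over the list alone 0 passed (camera adjusted p = 0.709). Ighm rose by 0.32 and lost its call with 32 added in linear units (0.31) and without GFP negative 1 (0.27), GFP negative 2 (0.29), GFP positive 2 (0.32) or GFP positive 3 (0.25). H2-Ab1 (0.40) did not pass, but was called higher with the replicate number as a block (limma adjusted p = 0.014), with a robust prior that follows intensity (adjusted p = 0.044), with array weights (adjusted p = 0.046) and with the filter at a level of 5 (adjusted p = 0.044). Of 10 myeloid markers, Ctss (0.66) and Cd68 (1.11, from 1.76 ± 0.23, and 0.15 with 32 added) rose and Fcer1g fell, by 0.54 (-0.08 in that setting; camera adjusted p = 0.855). Csf1r (-0.32) did not pass, but was called lower with the replicate number as a block (limma adjusted p = 0.024) and in several other settings. Among these were quantile normalization (limma adjusted p = 0.035), array weights (0.039) and leaving out GFP positive 1 (0.013). Lyz2 stayed near background at 1.77 and 1.79.

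Of 7 dendritic cell markers, 2 rose and 4 fell (camera adjusted p = 0.637). Bst2, which is also an interferon-response gene, rose by 0.44 and Cst3 by 0.26, and H2-DMb2 changed by -0.54 (-0.15 with 32 added in linear units), but without GFP negative 1 and GFP positive 3 these counts were 0 and 1. Cst3 lost its call with the replicate number as a block (limma adjusted p = 0.056), after quantile normalization (0.19) or median centring (0.15), and without GFP negative 1 or 3 or GFP positive 1 or 3 (0.23 to 0.25). Of 6 CD4 and regulatory T cell markers, Ikzf4 (0.96) and Zbtb7b (0.42) rose and Ctla4 (-0.63) fell (camera adjusted p = 0.999). With 32 added in linear units these changes were 0.54, 0.12 and -0.57, and Ctla4 lost its call. Cd4 itself was at 2.87 and 2.82. Ctla4 lost its call without GFP negative 1 or 2 or GFP positive 1 or 3 (-0.71 to -0.40), and Zbtb7b without GFP negative 1 or 3 or GFP positive 2 or 3 (0.33 to 0.43). Platelet markers gave 2 of 5 lower, Itga2b and Treml1 (camera adjusted p = 0.243), and stromal markers 1 of 7 higher, Pecam1, by 1.16 (0.32 with 32 added; camera adjusted p = 0.709). Too few natural killer cell markers (3, with Fcer1g lower) and erythroid markers (2, with Epor lower) were tested for a list test, and Epor lost its call with 32 added (-0.07) and without GFP negative 1 or 3 or GFP positive 1 or 3 (-0.37 to -0.32). Klf1, the other erythroid marker (-0.25), did not pass. It was called lower with the replicate number as a block (limma adjusted p = 0.038) and after median centring (limma adjusted p = 0.049). Median centring, which moved the median change of all tested genes to -0.14, also gave calls of lower Csf1r, Cd79a, Ly6d, Tyrobp, Gp5, Col1a2, Dcn and Kdr. With 1 sample left out these small counts moved further. For example, 2 myeloid markers fell without GFP negative 2 or GFP positive 1, 2 dendritic markers fell without GFP negative 2, GFP negative 3 or GFP positive 3, and 1 stromal marker fell without GFP negative 3 or GFP positive 1. For the myeloid, dendritic, CD4, platelet, natural killer, erythroid and stromal markers the counts adjusted over the list alone were the same.

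For 5 lists the median, the mean and the direction of camera did not share a sign. The cytokine receptor, homing and CD4 lists had medians of -0.06, -0.01 and -0.10 and means of -0.07, -0.12 and -0.03 with an upward direction by camera. The myeloid and stromal lists had medians of -0.08 and -0.15, means of 0.04 and 0.02 and a downward direction.

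Control probe sets gave measures of RNA quality and labelling, each compared by a two-sided exact permutation test whose smallest possible p is 0.1. The signal at the 3' end minus that at the 5' end differed by 0.03 between groups for Gapdh (exact p = 0.5), 0.04 for beta-actin (exact p = 0.2) and 0.53 for the transferrin receptor (exact p = 0.2). Hybridization spike-ins were brighter in GFP positive samples, 8.30 ± 0.17 against 8.10 ± 0.04 (exact p = 0.1), with GFP positive 3 the highest at 8.50. Poly-A spike-ins read 5.02 ± 0.06 in GFP positive and 4.93 ± 0.06 in GFP negative samples, with overlap between the groups (exact p = 0.2). Compared within replicate numbers, hybridization and poly-A spike-ins were higher in GFP positive samples in all 3 pairs, by 0.08 to 0.43 and 0.06 to 0.13 (paired exact p = 0.25 for both, the smallest possible). The 18S ribosomal RNA signal was 8.95 ± 0.27 in GFP positive and 9.45 ± 0.56 in GFP negative samples (exact p = 0.2), with GFP negative 1 the highest at 9.98. Without those 2 samples 3325 genes changed, 2074 higher and 1251 lower, and the same 5 lists were called by camera. Of the named genes 48 lost their call in that setting, among them Cd27, Aldoa, Il10, Hdac6, Bst2 and Treml1.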

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

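The tests of the Mycn and interferon patterns were chosen only after the results were seen.

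Of 3363 tested probe sets that the pairing table does not list, which enter no gene comparison, 812 passed the threshold, 518 higher and 294 lower in GFP positive samples. They are listed as a signal in data that the gene comparisons did not use. The share was 24.1%, against 33.8% of probe sets with a gene name. No biological explanation was tested.

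The rise of the brightest Mycn probe set, by 6.15, stands against the fall of a second. A higher level of the whole transcript would raise the other Mycn probe sets, and the second changed by -2.47, which argues against it. RNA of the retroviral construct read by the brightest probe set is a candidate explanation. The lowest GFP positive sample lay 5.62 above the highest GFP negative one, but any cause of so large a rise would give that gap. The construct explanation stays open, because neither the probe nor the vector sequence was used here. A different form of the transcript in cells with the mutant is also open and was not tested.

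The interferon-response list was higher in GFP positive cells. A level trend left by the normalization is argued against by cyclic loess normalization, after which the list median was 1.27 and the list was still called at the preset correlation; as deposited, it was not called with an estimated correlation (adjusted p = 0.759). Myeloid, dendritic or B cells in the sort would raise the markers of their type along with the interferon genes. The 5 such markers with a level of at least 5 were all higher, Ctss by 0.66, Bst2 by 0.44, H2-Ab1 by 0.40 (not past the threshold), Ighm by 0.32 and Cst3 by 0.26, and of the dimmer ones Cd68 rose by 1.11, each less than the interferon median of 1.34. Yet the fixed lists of 10 myeloid, 7 dendritic and 9 B cell markers had medians of -0.082, -0.22 and -0.15 (SD of 0.49, 0.39 and 0.38 between members), each below the interferon median by more than that spread. These medians rest mostly on markers of low level. They lie near those of all tested genes at such levels, -0.14 under a level of 2 and -0.12 from 2 to 3. The comparison of medians is therefore weak evidence, and the 5 brighter markers went the other way. The values argue at most against such cells as the whole cause, and a smaller share of them stays open. Infection with a retrovirus rather than the HDAC7 mutant could give the same median of 1.34 and cannot be told apart from the mutant's effect, since no array of cells with an empty vector is among the 6. An effect of the mutant itself therefore remains a hypothesis.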

How the results depend on the processing

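The filter at a level of 5, cyclic loess normalization and leaving out GFP negative 1 with GFP positive 3 were chosen after seeing the data. The probe sets of Hdac7 and Il2ra kept their direction and call in each setting run on single probe sets, except that the second Hdac7 probe set (-0.55) lies under a 2-fold minimum, a setting added for them after seeing the data, as was a threshold of 0.1. Of 227 named genes, 147 were tested in all 19 settings, and 105 of these kept their direction and side of the threshold in each. Signs turned only with other probe sets of a gene: Ighm gave -0.076 with the mean and -0.37 with the most variable probe set, Bcl2 0.12 and 0.59, and Nt5e -0.061 with the mean. Over all genes, 17 were called in both fits with opposite signs when the most variable probe set was used.

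The number of genes changed was 703 with a 2-fold minimum (487 higher, 216 lower; 1261 probe sets against 8786) and 3325 without both arrays, a setting with fewer samples (2074 higher, 1251 lower; 4374 probe sets), with 58.3% of the genes called again. Leaving out 1 array gave 4315 to 5604. Median centring raised the number lower to 3819, since it moved the median of all genes to -0.14. The filter at a level of 5, which tests fewer genes, gave 1424 lower and 5532 probe sets. Lists called were 3 with the filter at the 60th percentile, 3 with the filter at a level of 5, 0 with an estimated correlation and 9 with fry, against 5; the cause was not tested. With the replicate number as a block, 5858 genes changed, the list calls were the same, and of the named genes 4 lost and 3 gained a call. Of 227 named genes, 110 moved by more than 1.5 times with 32 added in linear units, which by its construction shrinks changes at low levels and does not measure signal over background. Near the TrpnX level (0.64 in GFP negative samples), as for Cdh1 at 0.90, no fold can be measured.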

Other observations

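The 11 further lists described first were written after the main results were seen but before their members were looked at, and the cyclic loess and spike-in tests of the level trend were chosen after the results were seen. Adjusted camera p-values of the further lists were computed over those lists alone, apart from the fixed lists.

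Genes of ribosome biogenesis were lower in GFP positive cells throughout, with 26 of 26 lower and a median of -0.77 (camera adjusted p = 1.0e-13, and adjusted p = 0.169 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, changed by -1.40, and the assembly genes Rrs1 and Nop16 by -1.29 and -1.14. Of 14 tRNA synthetase genes 11 fell and 0 rose (median -0.45, camera adjusted p = 3.7e-04, and adjusted p = 0.233 with an estimated correlation), and of 17 oxidative phosphorylation genes 5 fell and 0 rose (median -0.14, adjusted p = 0.0076, and 0.169 with an estimated correlation). ER chaperone genes gave 7 falls, among them Sdf2l1 (-0.92), and 1 rise, Edem1 (0.89), of 13 (adjusted p = 0.014, and 0.169 with an estimated correlation).

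Other lists were higher. Of 15 MHC class I presentation genes 11 rose and 0 fell, with Tap2 at 1.00 and Tapbp at 0.94 (camera adjusted p = 0.0021, and adjusted p = 0.189 with an estimated correlation). Targets of FOXO factors gave 8 rises and 1 fall of 15, with Pik3ip1, an inhibitor of PI3 kinase, at 2.44, Ccng2 (cyclin G2) at 2.08 and Cdkn1b (p27) at 1.01 (adjusted p = 0.0056, and 0.169 with an estimated correlation). Lysosome genes gave 9 rises and 1 fall of 16 (adjusted p = 0.0027), and targets of NF-kB 6 rises and 0 falls of 10 (adjusted p = 0.0019), each with an adjusted p of 0.189 with an estimated correlation. Targets of p53 gave 2 rises and 2 falls of 10 (adjusted p = 0.707). Of the list of 10 natural killer family receptor genes, only Klrg1 was tested, and it did not pass (-0.12). Klrk1, given above among the largest falls, was not counted in that list.

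Because Itgae, Cdh1 and Tgfbr1 rose, a wider rise of TGF-beta and SMAD pathway genes was proposed as a hypothesis and tested on a list without those 3 genes. The list had a median of 0.68, with 8 of 14 higher and 1 lower (camera adjusted p = 0.026). This met the prediction at the preset correlation, with the p adjusted over the further lists alone. The unadjusted camera p was 0.024. An adjustment together with the fixed lists was not run, so whether the call would hold under it is open. Pmepa1 at 2.08 and Skil at 1.03 were among the rises, and Ltbp3 (-0.25) was the member lower. The 5 that did not pass included Smad7 at -0.10, Bambi at -0.38 and Tgif1 at -0.32. The list did not pass with an estimated correlation (adjusted p = 0.169), and the test does not show that the pathway is active. The further lists were run only on the values as deposited, without the other filters or normalizations.

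Genes of low level tended to be lower and genes of middle level higher in GFP positive samples, with medians of -0.14 under a level of 2 and 0.15 between 5 and 7. A level trend left by the normalization may contribute, since cyclic loess normalization narrowed the gap between genes of level 5 to 7 and those under 3 from 0.29 to 0.114, which leaves it open. A difference in hybridization is another candidate explanation, as it needs hybridization spike-ins that do not overlap between the groups, and they did not (0.195 higher, exact p = 0.1). That is the smallest p possible, and exchangeable samples, 3 against 3, separate by chance in 10% of cases. Within replicate numbers the hybridization spike-ins were higher in all 3 pairs (paired exact p = 0.25, the smallest possible). A difference in labelling stays open, since the poly-A spike-ins were 0.0899 higher with overlap between the groups (exact p = 0.2) and higher in each of the 3 replicate pairs (paired exact p = 0.25, the smallest possible). An effect of the mutant on abundant and rare transcripts was not tested.

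The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5557 genes and the highest of the other splits 0, and 1 of the 10 splits, the real one, gave as many. Of the 4 splits that part all 3 pairs of equal replicate number, the real one gave 5557 genes. The other 3 gave 0, as did the 6 splits that part 1 pair. Each split but the real one mixes both groups, so the difference between the groups enters its spread and leaves few or no calls. These counts of 0 therefore do not show what chance alone would give.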
